A study of Mus musculus with 2 samples.

How the data were processed

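Pools of forebrains from 24 and 34 mouse embryos at embryonic day 14.5 were profiled by ATAC-seq, as replicates 1 and 2 of 1 group. DNA was fragmented by Nextera tagmentation, per the labels. The deposited files were lists of open regions on mm10, 3 for each library and 6 for both libraries together. The aligner, the peak caller, their versions, the handling of duplicates and any shift of reads for the transposase are not given in the sources used here. Per the readme texts among the deposited files, the lists of each library were made from that library's alignments and the pooled lists from the alignments of both. Thresholded, pseudoreplicated and replicated lists were also derived from a further file that those texts name only by its accession. In the data, these lists hold the regular chromosomes only.

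The authors gave each summit a signal value, a −log10 p and a −log10 q in narrowPeak layout, of which the −log10 q was not used. The quantity behind the deposited signal value is not named in the files, so signal was used to rank and describe regions within a list. The exceptions are the rank correlation of shared regions, the choice of named genes by their mean signal over both libraries, and 1 test of depth. That test paired regions of like signal across the libraries and so assumes that both lists use the same scale. The deposited ranked lists hold a score per peak that reached 540 at an IDR of 0.05, which was used to compare the ranked with the thresholded lists. IDR is the share of irreproducible calls expected among peaks ranked at least as high. The authors' pseudoreplicated lists, the lenient lists here, come from splits of the reads of a library or of the pool, as their name says. None of the files holds a read total, so depth per library is unknown, and no interval or floor that needs it was computed.

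Lines with the same start and end were joined into 1 region that kept the summit of highest signal, and overlapping regions were merged. Regions were called shared when at least 50% of either region was covered (bedtools 2.31.1), and chance sharing was taken from 100 placements of the regions at random starts on the same chromosome. Summits were assigned to a promoter (within 1000 bp of any annotated start site), exon, intron or intergenic sequence with the GENCODE vM21 annotation of the same assembly. A gene had a promoter region when a summit lay within 1000 bp of any of its start sites. The CpG content of a promoter was counted within 500 bp of the start site, in 10 bins. Distal regions were assigned to the nearest protein-coding start site within 100 kb. Each of 21 gene lists was compared with 10000 random lists of the same size, matched in 10 bins on CpG content for promoters and on territory size for distal regions. The territory is the stretch nearest to the gene's start sites. The percentile counts ties at their middle. All genes of the lists were matched in the annotation. The 20 consensus motifs were searched on both strands without mismatch within 100 bp of the summit and in windows of the same size 2000 bp to either side. A motif was called above or below the flanks when the 95% Wilson intervals of the shares did not overlap. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and blastn 2.17.0 were used.

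Gene lists, motifs, intervals, tests and most alternatives were fixed before the data were examined. Named genes followed a fixed rule: in each list up to 4 members with a promoter region in both libraries and the highest mean signal over them, and up to 3 members without one in either library, in list order. To these were added the 10 genes with the most distal regions, the 5 distal regions of highest signal, the 3 regions of highest signal in each of 7 intervals and up to 5 promoter regions found in a single library. The overlap, random-list and motif steps were tested on simulated data: 600 of 600 planted overlaps among 1000 regions were recovered, 1.5% of 200 unchanged lists of 20 genes lay above the central 95% of random lists, 98.0% of 50 lists with 12 planted genes did, and 300 of 300 planted motifs were found. The planted motif was an exact CTCF match and the simulated genes were independent. These runs thus check the code and do not cover lists of clustered genes.

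Alternatives covered the overlap rule, the authors' threshold, list length, the promoter window, the distance limit, the motif window and flanks, and leaving out each library. Any summit or any overlap at promoters, the rank agreement over single lines, and shuffled windows as motif background, were added after the data were seen. Pooled lists were not treated as a further replicate. No test between libraries or groups was made, since the design has 1 group and 1 library per replicate. The per-input columns of the ranked lists were not used.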

Results

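Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in the forebrain of mouse embryos at embryonic day 14.5. The 2 libraries were biological replicates of 1 group. Replicate 1 was a pool of forebrains from 24 embryos and replicate 2 a pool from 34 embryos, of both sexes, on the B6NTac;B6NCrl/Lap background. No second tissue, stage or treatment was labelled, so the comparisons were between the replicates, between kinds of region and between fixed lists of genes. The lists of open regions gave no read totals, so the depth of each library is unknown. After lines that described several summits of 1 region were joined, the list thresholded on the irreproducible discovery rate (IDR) held 21074 regions in replicate 1 and 33208 in replicate 2. They covered 21.2 Mb and 31.6 Mb, with a median width of 1008 bp and 933 bp. All coordinates below are on mm10.

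Nearly the whole list of replicate 1 recurred in replicate 2. Of the 21074 regions of replicate 1, 20098 (95.4%) were found in replicate 2, whereas 20057 of the 33208 regions of replicate 2 (60.4%) were found in replicate 1. Random placement of the regions on the same chromosomes gave 1.53% and 0.971% on average over 100 placements, and at most 1.71% and 1.09%. Across the 20098 shared pairs, the ranks by signal value had a Spearman rho of 0.869, a value across regions of 1 pair of libraries, not across samples. With every summit line taken as its own region rho was 0.269, because each line of a region was then paired with the strongest line of its counterpart. Sharing differed between kinds of region, which were not compared at like signal. Promoter regions of replicate 2 were found in replicate 1 for 12126 of 14096 (86.0%), and regions away from start sites for 7931 of 19112 (41.5%). The promoter regions of replicate 2 were also stronger, with a median signal value of 10.5 against 7.44, so kind and strength were not separated. In the other direction the shares were 98.2% of 12364 promoter regions and 91.3% of 8710 distal regions. With 1 library on each side, no test between the libraries was possible.

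The share of promoters differed between the libraries. The summit lay within 1000 bp of an annotated transcription start site for 58.7% of regions in replicate 1 and 42.4% in replicate 2. Among the 21074 regions of highest signal in replicate 2, as many as in replicate 1, it was 51.7%. In the conservative list that the authors made from both libraries together, 31966 regions were divided into 44.8% promoter, 2.66% exonic, 26.9% intronic and 25.6% intergenic. Regions of replicate 2 that were found in replicate 1 were promoters in 60.5% of cases, against 15.0% of the 13151 regions that were not found there. The latter were mostly intronic (42.4%) or intergenic (39.6%), with a median −log10 p of 31.4 against 104 for the found regions. The promoter share of the authors' lenient pooled list was lower, at 24.0%.

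**Figure D1:**
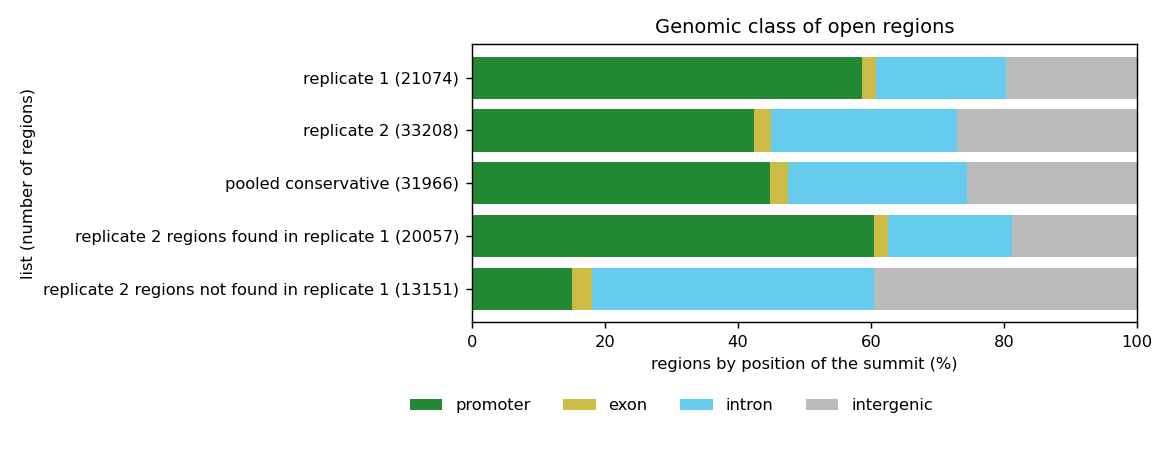
Share of open regions (x axis, percent) whose summit lay in a promoter, exon, intron or intergenic sequence, for each list (y axis, number of regions in parentheses). Promoters formed 60.5% of the replicate 2 regions found in replicate 1 and 15.0% of those not found.

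Pan-neuronal and synaptic genes had open promoters in both libraries. All 16 genes of this list did, more than in any of 10000 random lists of protein-coding genes matched on promoter CpG content, whose mean was 9.57 genes. The promoter of Syt1, a synaptic vesicle calcium sensor (10:109010247-109011761), had a signal value of 15.0 in replicate 1 and 20.6 in replicate 2. Nrxn1, a presynaptic adhesion protein, had 13.3 and 14.7, Syn1, a synaptic vesicle phosphoprotein, 12.4 and 15.2, and Map2, a dendritic microtubule protein, 10.7 and 12.1. Signal values are the authors' and rank regions within each list. Of the radial glia and progenitor genes, 15 of 16 had a promoter region in both libraries (percentile 95.3, within the central 95% of the random lists). The percentile was 99.1 in replicate 2, where all 16 had one, and 67.2 with a promoter window of 500 bp. Id4, an inhibitor of basic helix-loop-helix factors, reached 10.7 and 10.8 at 13:48260433-48261770. Sox2, a transcription factor of neural stem cells, had 8.85 and 8.86 at 3:34649217-34650608, and Sox9 and the intermediate filament gene Vim had 8.17 and 8.97, and 8.08 and 8.93.

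The lists for neurogenesis, cortical projection neurons and telencephalic patterning were within the central 95% of the random lists when both libraries were required, though not under every alternative. For neurogenesis and intermediate progenitors, 10 of 13 genes had promoter regions in both libraries (percentile 37.8), led by Elavl4, a neuronal RNA-binding protein, with signal values of 11.3 and 12.6 at 4:110350860-110352330, and by Btg2, Sox11 and Sox4. The proneural gene Neurod4 had none in either library. For cortical projection neurons the count was 14 of 18 (percentile 60.3). Zbtb18, a transcriptional repressor, had the highest values (12.6 and 13.7, at 1:177441407-177442914), followed by Pou3f1, Nfia and Pou3f2. The Nfia regions of the libraries lay at different start sites. The vesicular glutamate transporter gene Slc17a7 had no promoter region in either library. In replicate 2 alone 17 of the 18 genes had one (percentile 97.8), the additional genes being Tbr1, Bcl11b and Neurod2. For telencephalon and forebrain patterning the count was 12 of 16 (percentile 14.6). Gli3, a mediator of hedgehog signalling, had 9.27 and 9.62 at 13:15462692-15464514, Lhx2 8.42 and 9.30, Foxg1, a telencephalic regulator, 8.01 and 9.10 at 12:49383269-49384768, and Dmrta2 7.65 and 8.90. Otx2, Nr2f2 and Fezf1 had none in either library. Among the 20000 regions of highest signal in each library, these 3 lists and the radial glia list held 5, 9, 5 and 8 genes, in the order neurogenesis, cortical, telencephalic and radial glia. The neurogenesis and telencephalic lists then lay below the central 95% (percentiles 0.835 and 0.015), as did the Cajal-Retzius and mature astrocyte lists with 3 and 0 genes (percentiles 1.68 and 0.425).

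Genes of the ganglionic eminence and GABAergic neurons fell just below the central 95% of the random lists, and most alternatives removed this. Promoter regions were found in both libraries for 13 of 20 genes (percentile 1.86). The percentile was 4.81 in replicate 1 alone, 4.31 in replicate 2 alone, and 4.39 and 4.80 with promoter windows of 500 bp and 2000 bp, all within the central 95%. Ebf1, a transcription factor of striatal neurons, had signal values of 13.1 and 12.1 at 11:44616750-44617584, Isl1 10.0 and 12.4, Foxp2 8.32 and 10.4, and Sp9 8.18 and 9.33. Gad1, which encodes a GABA-synthesising enzyme, Nkx2-1, a medial eminence regulator, and Gsx1 had none in either library's own list. In the authors' lenient lists all 20 genes had a promoter region in both libraries (percentile 86.0), and among the 20000 regions of highest signal 6 had one (percentile 0). The Cajal-Retzius list held 5 of 9 genes (percentile 4.95), with Ebf2 at 7.65 and 11.1, Calb2 at 8.27 and 9.86, Reln, the secreted glycoprotein of these cells, at 6.56 and 7.51, and Ebf3 at 6.91 and 7.01. Trp73, Lhx5 and Nhlh2 had none in either library.

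Genes of the diencephalon and of more caudal regions were mostly without promoter regions. In the diencephalon list 4 of 13 genes had one in both libraries (percentile 0.005), and 9 in the lenient lists (percentile 0.92). They were Pitx2 (11.6 and 16.2), Sim1 (12.3 and 12.9), Tcf7l2 (7.53 and 7.91) and Lhx9 (3.92 and 4.97), while Gbx2, Rax and Fezf1 had none in either library's own list. In the hindbrain and spinal cord list 2 of 23 genes had a promoter region in both libraries, fewer than in any of the random lists, whose mean was 16.7 genes. These were Egr2, a regulator of the hindbrain segments, with 6.48 and 8.38, and En2 with 7.48 and 6.26. Neither is a Hox gene, whereas most members of the list are. Hox genes lie in clusters, and the random lists drew genes without regard to neighbours. The low count thus rests mainly on Hox clusters, and the other members are too few to speak for caudal genes in general. Hoxa2, Hoxa3 and Hoxa4 were among the 20 genes with none in either library. The lenient lists held 5 of the 23, again fewer than any random list.

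**Figure D2:**
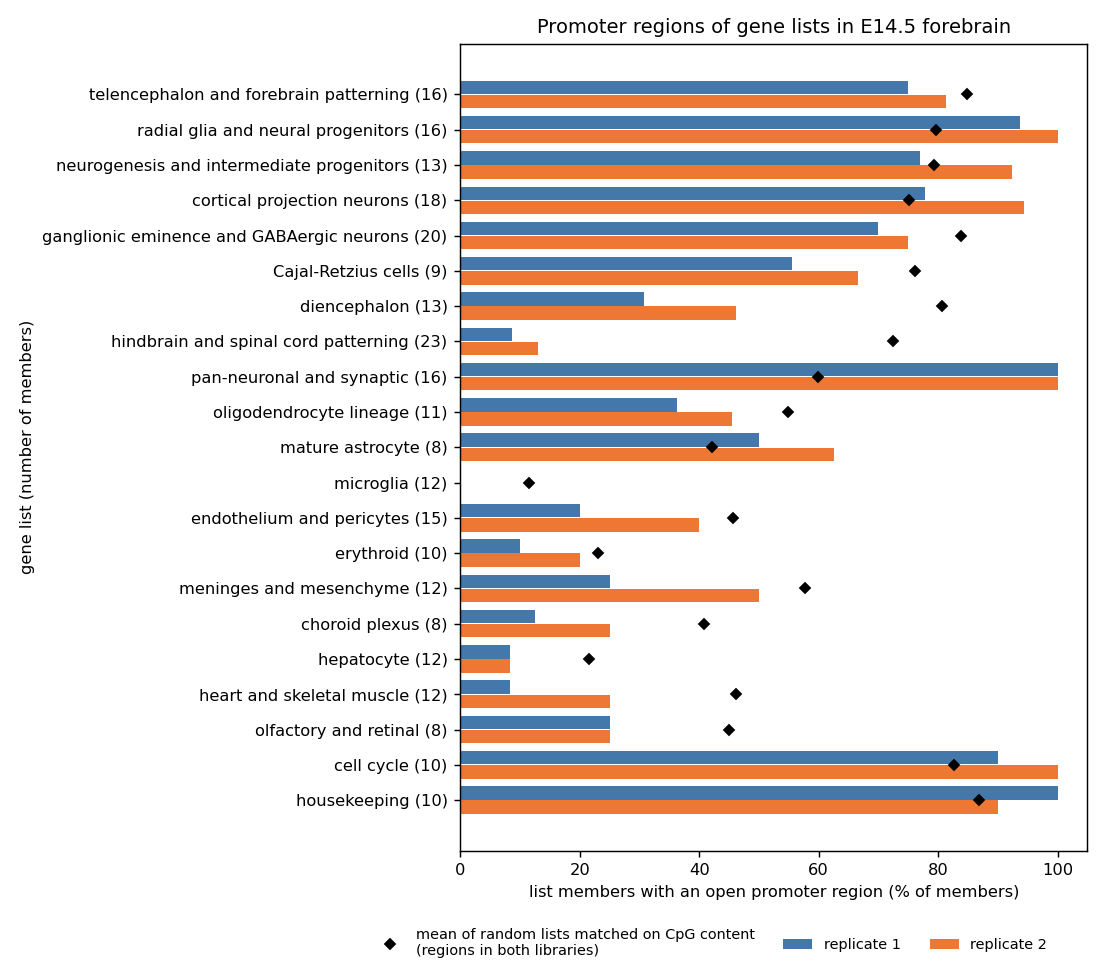
Percent of the members of each gene list (x axis) with an open promoter region in replicate 1 (blue) and replicate 2 (orange), 1 library each. Diamonds give the mean of 10000 random lists matched on promoter CpG content, for regions in both libraries. They are thus a stricter measure than the bars of single libraries. The pan-neuronal list reached 100% in both libraries, and the microglia list had none.

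Markers of glia, vessels and mesenchyme were compared in the same way. Of the oligodendrocyte lineage genes 4 of 11 had promoter regions in both libraries (percentile 5.77): Olig2, a progenitor transcription factor, with 10.7 and 10.8, Olig1 with 8.75 and 9.67, Pdgfra with 8.88 and 9.24, and Mbp with 5.43 and 5.97. Sox10, Cspg4 and Nkx2-2 had none in either library. Of the mature astrocyte genes 4 of 8 had one (percentile 70.9), with Aldoc at 7.79 and 6.60 and Slc1a2, a glutamate transporter, at 7.01 and 6.21, then Gja1 and Fgfr3. Gfap, Aqp4 and S100b had none in either library's own list. None of the 12 microglia genes, among them Aif1, Csf1r and Cx3cr1, had a promoter region in either library. Random lists matched to these CpG-poor promoters averaged 1.39 genes (percentile 10.9, the lowest this list could reach), and 1 gene was found in the lenient lists. Endothelium and pericytes had 3 of 15 (percentile 0.59), namely Erg, Kcnj8 and Kdr, with Cldn5, Pecam1 and Cdh5 in neither library. Meninges and mesenchyme had 3 of 12 (percentile 0.11), namely Tbx18, Foxc1 and Prrx1, with Foxc2, Col1a1 and Col3a1 in neither library's own list. In replicate 2 alone these last lists each held 6 genes (percentiles 12.3 and 10.6), and in the lenient lists 7 and 8 (percentiles 13.2 and 49.7), all within the central 95%.

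The remaining lists served as a wider reference. Choroid plexus genes had promoter regions in both libraries for 1 of 8 (Foxj1, percentile 1.45, with Ttr, Aqp1 and Clic6 in neither library's own list), erythroid genes for 1 of 10 (Gypa, percentile 10.8, with Hba-a1, Hbb-bt and Gata1 in neither), hepatocyte genes for 1 of 12 (Apob, percentile 8.33, with Alb, Afp and Apoa1 in neither) and heart and skeletal muscle genes for 1 of 12 (percentile 0.06, with Myh6, Myh7 and Nkx2-5 in neither). The muscle gene was Actn2, which encodes an actin-crosslinking protein, with 15.0 and 17.6 at 13:12340132-12341275. The lenient lists held 4, 3, 3 and 5 genes of these lists, and replicate 2 alone 2, 2, 1 and 3. The choroid plexus percentile was 5.38 in replicate 2 alone and 48.7 in the lenient lists, and that of heart and muscle 6.61 in the lenient lists, all within the central 95%. The hepatocyte percentile was 1.18 with a window of 500 bp. The olfactory and retinal list had 2 of 8 (Adcy3 and Nrl, percentile 8.36, and 0.985 in the lenient lists), with Omp, Cnga2 and Crx in neither. Cell cycle genes had 9 of 10 (percentile 69.7), with Ccna2 at 17.0 and 18.6, Bub1 at 14.5 and 18.8, Ccnb1 at 14.5 and 18.0 and Pcna at 14.1 and 17.0. Housekeeping genes had 9 of 10 (percentile 57.2), led by Rplp0 (15.1 and 17.0), Hprt, Eef1a1 and Polr2a. Over the 21 lists, 1 lay above and 7 lay below the central 95% of the random lists. In replicate 2 alone the counts were 3 and 3, and in the lenient lists 1 and 3. Genes are not replicates, so these percentiles describe the libraries and are not p-values.

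In the full lists, which differ in length, promoter regions in a single library came nearly always from replicate 2. Over the 269 different genes of the 21 lists, 26 had a promoter region in replicate 2 alone and 2 in replicate 1 alone. The highest signal values were those of Epor, the erythropoietin receptor gene (7.75, at 9:21962008-21962908), Tbx20 (7.07, at 9:24774075-24774829), Aldh1l1 (6.96, at 6:90550224-90550875), Col1a2 (6.91, at 6:4504821-4505932) and Flt1 (6.76, at 5:147725056-147726135), all in replicate 2. Of the 112 list genes with no promoter region in either library's own list, 10 had one in the pooled conservative list. They were Gad1 (2:70561069-70561710, signal value 4.28), Gsx1 (5:147188431-147189371, 5.84), Gbx2 (1:89930873-89931605, 4.53), Gfap (11:102900777-102901174, 6.05), Col1a1 (11:94936791-94937981, 5.42), Aqp1, Afp, Sp8, Tmem119 and Dcn, the last 3 of them outside the naming rule and chosen after their values were seen. Over all 21938 protein-coding genes, 11764 (53.6%) had promoter regions in both libraries, 937 in replicate 2 alone and 119 in replicate 1 alone. The share with regions in both rose with promoter CpG content, from 0.0456% in the lowest of 10 bins of genes to 92.1% in the highest. With the 20000 regions of highest signal from each library the balance turned. Then 1355 genes had a promoter region in replicate 1 alone and 300 in replicate 2 alone.

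Regions away from start sites gathered near genes of the telencephalon. In the pooled conservative list 17641 regions were distal, and 13110 of them lay within 100 kb of the nearest protein-coding start site. Cortical projection neuron genes had 5.33 such regions per gene, 3.55 times the mean of random lists matched on the size of the gene's territory and more than any of 10000 such lists. The replicates alone gave 3.44 and 5.00 regions per gene, or 4.77 and 3.07 times their random lists. Ganglionic eminence genes had 3.05 regions per gene (2.87 times), also more than any random list, although fewer of their promoters were listed. Neurogenesis genes had 2.92 (3.32 times, percentile 99.97), telencephalic patterning genes 3.31 (2.65 times) and radial glia genes 3.38 (2.42 times). Among list members, Nfib, Mef2c, Nrxn1, Nfia, Foxp2 and Meis2 had 19, 13, 10, 10, 9 and 9 regions, members chosen after their values were seen.

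The other lists ranged from 2.72 times to 0.546 times their random lists. Mature astrocyte genes had 2.12 regions per gene (2.72 times, percentile 98.8), Cajal-Retzius genes 2.56 (2.28 times, percentile 98.4), pan-neuronal genes 2.38 (1.89 times, percentile 98.1) and oligodendrocyte genes 1.27 (2.27 times, percentile 98.0). In replicate 1 alone the astrocyte list was at 3.95 times (percentile 99.4) and in replicate 2 alone at 2.45 times (percentile 98.0). The Cajal-Retzius list, at 1.43 and 2.05 times (percentiles 78.3 and 97.4), and the oligodendrocyte list, at 1.65 and 1.92 times (percentiles 82.7 and 94.5), were within the central 95% in each library alone. Diencephalon genes had 1.62 (1.68 times, percentile 93.0, and 99.0 with a limit of 50 kb), choroid plexus genes 1.12 (1.36 times), heart and muscle genes 0.833 (1.39 times), endothelial genes 0.80 (0.847 times) and hepatocyte genes 0.667 (0.998 times). Cell cycle genes had 0.60 (2.29 times, percentile 93.0), microglia genes 0.50 (1.22 times), housekeeping genes 0.40 (1.61 times), olfactory and retinal genes 0.25 (0.682 times) and erythroid genes 0.20 (0.718 times). Mesenchyme genes had 0.583 (0.546 times, percentile 13.1), and hindbrain and spinal cord genes 0.217 (0.823 times). In replicate 1 and replicate 2 alone the hepatocyte list was at 0.257 and 0.708 times, the erythroid list at 1.45 and 0.703 times and the housekeeping list at 4.01 and 2.01 times (percentiles 97.9 and 89.0). The hindbrain list had 0 regions in replicate 1 and was at 0.833 times in replicate 2. In all, 9 lists lay above the central 95% of random lists and 0 below. Lists with few expected regions could hardly fall below. The hindbrain list, with 0 regions in replicate 1, was still at percentile 4.17 there. With a limit of 500 kb the astrocyte, Cajal-Retzius, pan-neuronal and oligodendrocyte lists were not above and 5 lists were, and with 50 kb the oligodendrocyte list was not (percentile 95.2). With the 20000 regions of highest signal 3 lists were above, namely those of cortical projection neurons, neurogenesis and radial glia.

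**Figure D3:**
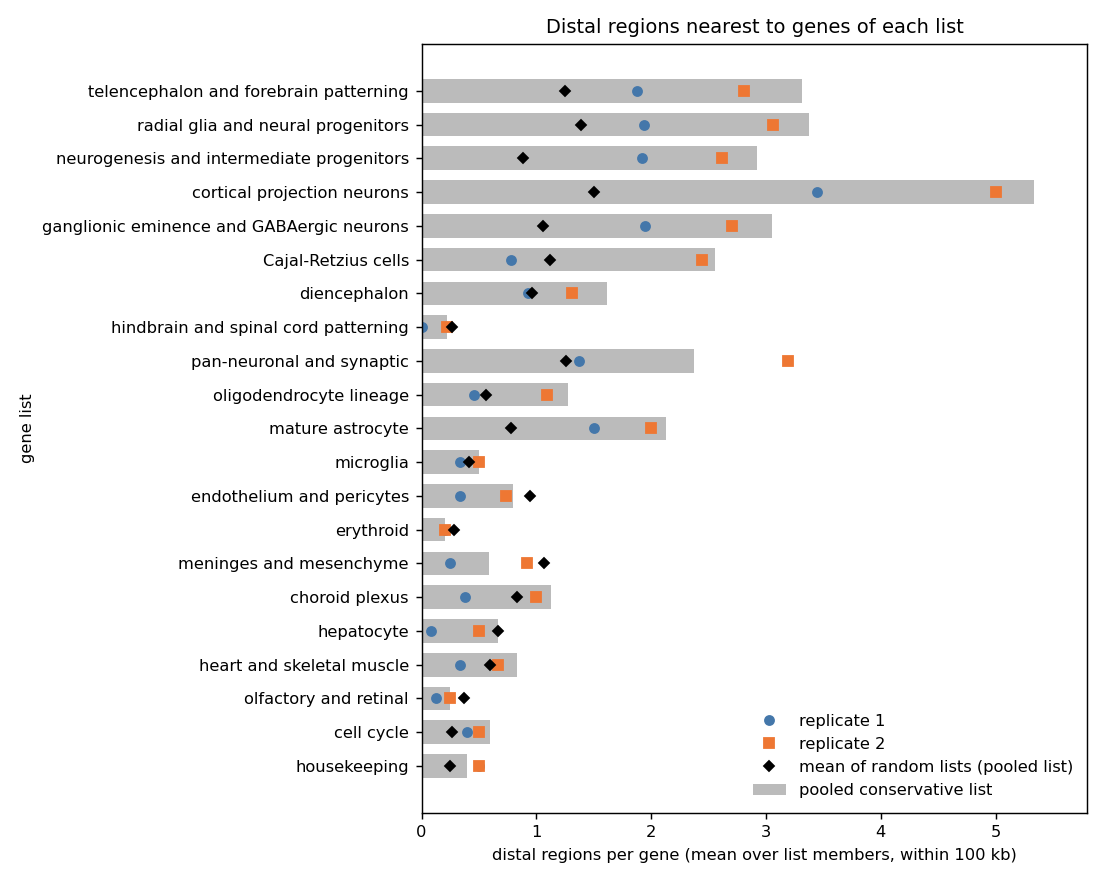
Mean number of distal regions per gene (x axis, within 100 kb) for each gene list, in the pooled conservative list (bars), replicate 1 (circles) and replicate 2 (squares). Diamonds give the mean of 10000 random lists for the pooled list. Cortical projection neuron genes had 5.33 regions per gene, 3.55 times the random lists.

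The genes with the most distal regions were mostly large. Gse1 had 24 (15 in replicate 1 and 19 in replicate 2), Tenm4, a teneurin adhesion protein, 22 (14 and 20), and Nfib, a nuclear factor I transcription factor, 19 (10 and 17). Bach2 had 17, the transcript E130114P18Rik, Celf4, an RNA-binding protein, and Pbx1, a homeodomain protein, 15 each, and Dscaml1, Pde4d and Cntnap2 14 each. Their territories spanned from 298 kb for E130114P18Rik to 1565 kb for Pde4d.

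Intergenic intervals beside forebrain regulators differed in length and in the number of regions, so the counts are not a contrast between intervals. Between Neurog2, a proneural gene, and Alpk1 (34.7 kb) there were 3 regions, at 3:127639850-127641220, 3:127646006-127646822 and 3:127651608-127652943, with signal values of 6.28, 8.19 and 8.23 in the pooled list. All 3 were found in both libraries. Downstream of Emx2 the interval to Rab11fip2 (438 kb) held 5, the highest at 19:59541367-59542784 (15.9), 19:59866220-59867183 (13.4) and 19:59697446-59698174 (10.8). The first of these was classed as intronic, and its nearest start site, of the processed pseudogene AC098733.1, was 1357 bp away. The interval from Foxg1 to Prkd1 (954 kb) held 22, of which the highest lay at 12:50295573-50296376 (13.1), 12:49649193-49650020 (12.1) and 12:49835982-49837161 (11.3). It includes 1 other annotated coding gene, Gm43517. From Sox2 to Atp11b (1102 kb) there were 25, the highest at 3:35225031-35226082 (10.1), 3:35353567-35354668 (9.81) and 3:34795415-34795992 (9.78), the last found in replicate 2 and not in replicate 1. The interval from Gsx2 to Pdgfra (74.4 kb) held 1, at 5:75084761-75085856 (4.71), found in replicate 2 and not in replicate 1. Between Dlx5 and Dlx6 (9.24 kb) the pooled list held 1 region, at 6:6871523-6872256 (2.77), 508 bp from a start site of the non-coding gene Dlx6os1 and not matched by a region of either library's own list. Replicate 1 listed 1 region in that interval, and replicate 2 listed 0. No region was listed between Dlx1 and Dlx2 (9.43 kb) in either library or in the pooled list.

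**Figure D4:**
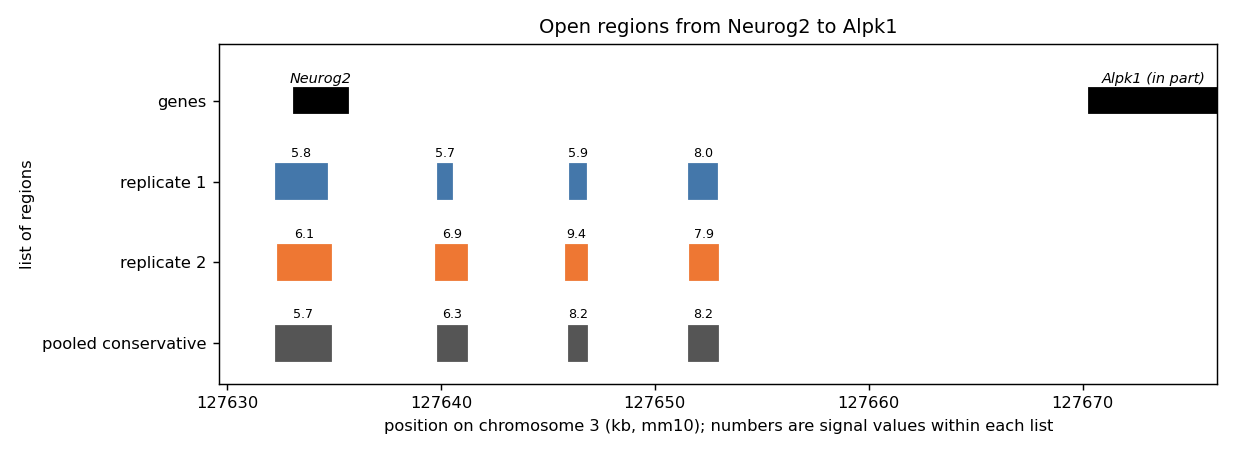
Map of the interval from Neurog2 to Alpk1 on chromosome 3 (x axis, kb, mm10) with the genes and the open regions of replicate 1, replicate 2 and the pooled conservative list (rows), drawn to scale. Numbers above the boxes are signal values within each list. The 3 intergenic regions were found in both libraries.

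The distal regions of highest signal value were narrow and were listed in both libraries. They lay at X:143482935-143483180 (signal value 55.4 in the pooled list, 246 bp wide, intergenic, 35532 bp from Pak3), 2:69355470-69355735 (51.9, 266 bp, intergenic, 12987 bp from Abcb11) and 2:3964420-3964690 (39.1, 271 bp, intergenic, 53158 bp from Frmd4a). The others were 5:60042765-60043140 (38.4, 376 bp, intergenic, 1765839 bp from G6pd2, the nearest protein-coding gene) and 10:96077546-96077951 (34.6, 406 bp, in an intron, 58942 bp from Gm5426). The median signal value of distal regions in this list was 6.92, and their median width 867 bp. The last 2 of these regions aligned to the mitochondrial genome over 89.1% and 86.7% of their length, and the region near Abcb11 over 48.5%.

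Sequence motifs were compared between summits and their flanks, for promoter and distal regions separately and without a test between these kinds. Shares are those of the pooled conservative list unless a library is named. At distal summits a match to the CTCF consensus lay within 100 bp in 7.40% of regions (95% Wilson interval 7.03 to 7.80), against 0.15% of flanking windows. In the libraries' own lists the CTCF share was 5.34% in replicate 1 and 5.51% in replicate 2, or 40.4 and 44.8 times the flanks. Both shares lay outside the interval, which does not cover differences between lists. The helix-loop-helix sites CAGCTG and CAGATG occurred in 22.9% and 24.3%, against 9.01% and 15.5% in the flanks. The homeobox core TAATTA occurred in 11.6% against 5.91%, the SOX site in 11.5% against 7.37%, the TTGGCA site of nuclear factor I in 19.6% against 10.1% and the POU octamer in 4.22% against 1.35%. In replicates 1 and 2 alone, CAGATG occurred in 23.5% and 26.7% of distal regions, and TTGGCA in 19.6% and 22.9%. The RFX site was found in 0.493% of distal regions (87 regions) against 2 flanking windows. The full nuclear factor I site occurred in 0.164% against 0.017%. At promoter summits the SP/KLF site stood out with 18.4% against 0.778%, with the ETS site (6.45% against 0.185%), the NFY site (9.84% against 2.03%) and the NRF1 site, found in 208 of 14325 promoter regions and in 1 flanking window. CTCF was found in 1.63% of promoter regions against 0.185%. The SP/KLF (2.36% against 0.59%), ETS, NFY (4.03% against 2.37%) and NRF1 sites were also above the flanks at distal summits, and the CTCF, RFX, CAGCTG and full nuclear factor I sites at promoter summits, so these 8 motifs were above the flanks at both kinds. The full nuclear factor I site had only 7 promoter matches and was not above shuffled windows there.

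The GATA, PU.1, AP-1, HNF4, TEAD and MEF2 sites were not above the flanks at distal summits. The GATA site of blood cell factors occurred in 0.34% of distal summits against 0.927% of flanks, and the PU.1 site of myeloid cells in 0.879% against 1.28%. The AP-1 (3.49% against 3.60%), HNF4 (0.193% against 0.258%), TEAD (11.5% against 10.7%) and MEF2 (0.108% against 0.045%) sites had overlapping intervals. REST matches were too few to compare, with 0 in promoter or distal summits. Of the 20 motifs, 13 were above and 2 below the flanks at distal summits, and 8 and 8 at promoter summits. Promoter summit windows had 64.9% G and C against 45.0% in their flanks, and distal ones 51.4% against 44.5%. Against shuffled copies of the summit windows that kept their dinucleotides, the counts were 15 and 1 at distal and 12 and 1 at promoter summits. TAATTA at promoters, 0.275 times the flanks, was then 2.74 times the shuffled windows, SOX at promoters went from 0.717 to 1.66 times, GATA at promoters from 0.22 to 1.21 times, TEAD from 0.635 to 1.01 times, AP-1 from 0.538 to 1.03 times, and PU.1 at distal summits from 0.687 to 1.09 times. Distal MEF2 and TEAD, within the spread of the flanks, were above the shuffled windows (3.45 and 1.13 times). The distal TTGGCA site, 1.94 times as frequent as in the flanks, occurred in 17.9% of the shuffled windows, and distal TAATTA went from 1.97 to 5.18 times. Distal CAGCTG went from 2.54 to 1.47 times, with 15.6% of shuffled windows, and the distal full nuclear factor I site from 9.67 to 3.62 times. At promoters SP/KLF went from 23.7 to 6.64 times, with 2.78% of shuffled windows, and ETS from 34.9 to 11.6 times, and the NRF1 site occurred in 0.0768% of shuffled windows. Distal GATA went from 0.367 to 0.659 times. Intervals cover the counting of regions only.

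**Figure D5:**
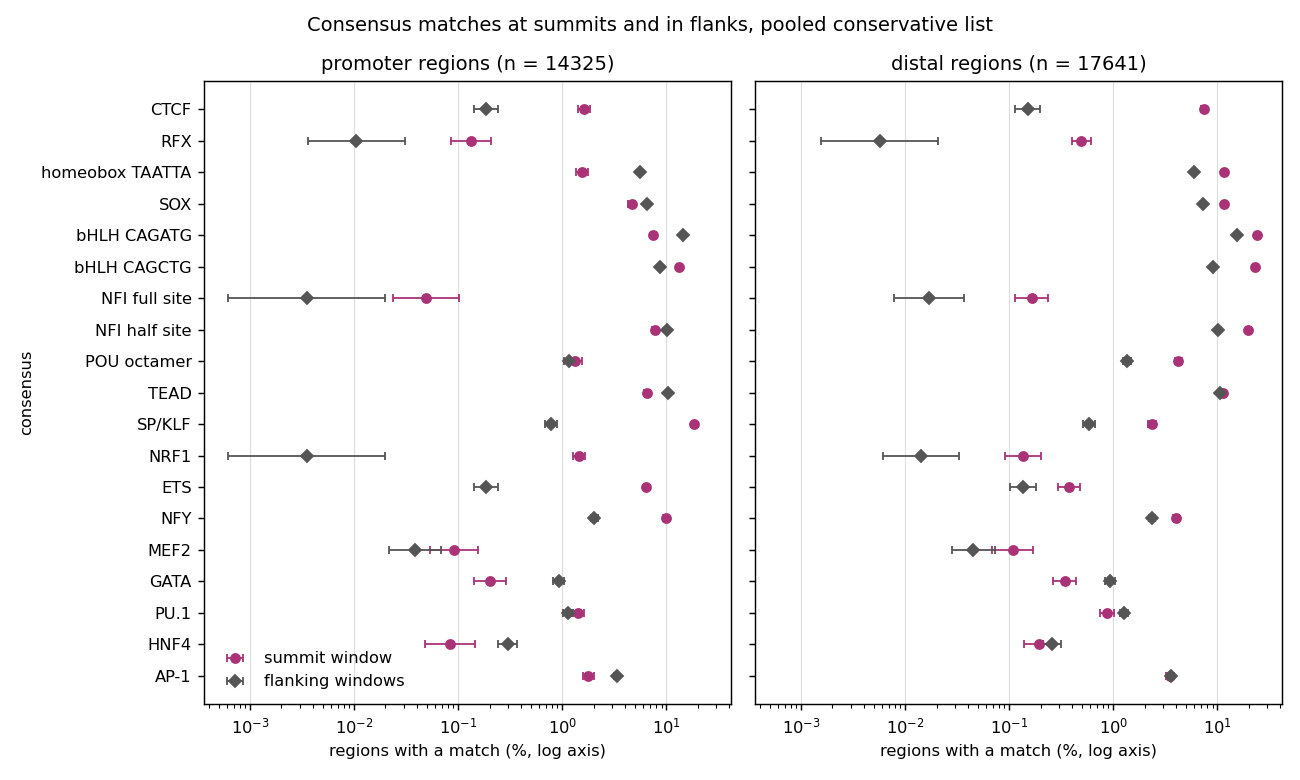
Percent of promoter regions (left) and distal regions (right) of the pooled conservative list with a consensus match within 100 bp of the summit (circles) and in flanking windows (diamonds), on a log axis with 95% Wilson intervals. CTCF at distal summits stood at 7.40% against 0.15% in the flanks, and at 5.34% and 5.51% in the own lists of replicates 1 and 2. The intervals do not cover such differences between lists. REST, with 0 summit matches, is not drawn.

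The lists that the authors made from both libraries differed in how far they rested on each library. Of the 31966 conservative regions, 62.1% were in both libraries' own lists, 22.8% in replicate 2 alone, 1.96% in replicate 1 alone and 13.2% in neither. For the 38923 regions of the pooled IDR thresholded list the shares were 51.2%, 30.1%, 2.19% and 16.5%. The replicated list held 71527 regions, of which 27.9% were in both and 53.5% in neither, and the lenient pooled list 83296, of which 23.9% were in both and 59.1% in neither.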

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

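The comparison of ranked with thresholded lists was chosen after the ranked lists had been seen, and no biological explanation was tested for it. The ranked lists hold lines that pass the IDR threshold of 0.05 and are missing from the thresholded lists used in the comparisons, a signal in data outside the main measurement. There were 171 such lines in replicate 1, 185 in replicate 2, 200 in the pooled conservative list and 230 in the pooled IDR thresholded list. Of these, 39, 47, 56 and 71 lay on contigs other than the regular chromosomes, and none on the mitochondrial chromosome. Every line of the thresholded lists was in the ranked lists. Of the 57 regions on the chromosomes left out of the pooled conservative list, 1 aligned to the mitochondrial genome over at least 50% of its length. It was also the widest, at 1:24611586-24616165 (4580 bp), and aligned along its full length at an identity of up to 99.96%.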

How the results depend on the processing

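Of the values under alternative settings for the main results, 191 stayed within their spread or within 1.5 times the count and 62 did not. The shuffled background, the rho over single lines and the other promoter rules were chosen after the data were seen. Unless stated, the cause was not tested. The shares of replicate 1 regions found in replicate 2 and of replicate 2 regions found in replicate 1, with rho, were 92.0%, 58.4% and 0.877 with a reciprocal overlap of 50%, and 85.5%, 54.3% and 0.876 with summits within 100 bp. They were 90.7%, 62.6% and 0.808 in the lenient lists, 77.4%, 77.2% and 0.818 for the 20000 regions of highest signal, and 76.4%, 75.9% and 0.820 for lists of equal length, where the construction removes the difference in length. With every line as its own region the shares were 96.8% and 68.4% and rho fell to 0.269, by construction, since each summit of a region was paired with the strongest summit of its counterpart. The promoter share was 24.0% in the lenient pooled list and ranged from 42.4% to 58.7% when either replicate was left out. With a reciprocal overlap, 49.2% of the pooled IDR thresholded, 59.7% of the conservative, 26.8% of the replicated and 23.0% of the pseudoreplicated regions were in both libraries.

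For promoters of the gene lists, the lenient lists gave 20 ganglionic eminence, 9 diencephalon, 5 hindbrain, 1 microglia, 7 endothelium, 3 erythroid, 8 mesenchyme, 4 choroid plexus, 3 hepatocyte and 5 heart and muscle genes, with 3 lists below the central 95% of random lists. The 20000 regions of highest signal gave 5 telencephalic, 8 radial glia, 5 neurogenesis, 9 cortical, 6 ganglionic eminence, 3 Cajal-Retzius, 1 hindbrain, 0 astrocyte, 1 mesenchyme and 1 olfactory and retinal gene. A window of 500 bp gave 0 hepatocyte genes, and a window of 2000 bp gave 2 erythroid and 2 hepatocyte genes, as did any overlap with the promoter window (2 and 2). Leaving out either replicate gave ranges of 3 to 6 endothelium, 1 to 2 erythroid, 3 to 6 mesenchyme, 1 to 2 choroid plexus and 1 to 3 heart and muscle genes, with 1 to 3 lists above and 3 to 6 below the random lists. For distal regions 5 lists lay above with the limit of 500 kb and 3 with the 20000 regions of highest signal.

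For motifs, 1 lay below at promoter summits and 1 at distal summits against shuffled windows, and 1 at distal summits with a window of 50 bp. Against shuffled windows the promoter ratios that turned were 2.74 (TAATTA), 1.66 (SOX), 1.01 (TEAD), 1.21 (GATA) and 1.03 (AP-1), and the distal one 1.09 (PU.1). Of the values of single lists and motifs, 157 stayed and 166 moved without turning. Overlap and rho need both libraries and have no value with a replicate left out. No paired analysis was possible because there is 1 group. Depth is not known, so absence from a list cannot be read as closed chromatin.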

Other observations

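The gene families, the tests of weaker regions, of the regions near Pak3 and Frmd4a, and of the lenient lists were chosen after the data had been seen. Gene families were compared with random lists in the same way. These random lists too drew genes without regard to neighbours. For families whose members lie in clusters, the percentiles thus treat neighbouring genes as if they were independent. Of 79 ribosomal protein genes, 76 (96.2%) had promoter regions in both libraries, and of 40 proteasome subunit genes 37 (92.5%), against means of 65.3 and 30.7 in 2000 random lists matched on CpG content (percentiles 99.95 and 99.8). Of 64 replication-dependent histone genes 55 did (percentile 96.3). Of 1135 olfactory receptor genes none had one in both libraries, against a random mean of 12.8, and 5 had one in replicate 2. Vomeronasal receptors had 1 of 331 (random mean 1.60, percentile 28.7).

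Some other families lay below all or nearly all of their random lists. The limit on clustered genes applies here too, among others to the Hox genes and the clustered protocadherins. Of 57 clustered protocadherin genes, adhesion proteins that neurons use in different combinations, 4 had promoter regions in both libraries, against a random mean of 19.5. In the lenient lists 5 had one. Of 39 Hox genes, which include those of the hindbrain list, 1 had one in both libraries, against 30.5, and 8 had one in the lenient lists. Keratins had 1 of 53 (random mean 13.6). Calcium channel subunit genes had 12 of 26 in both libraries (random mean 19.4), with 18 in replicate 2 and 22 in the lenient lists. All random means here are for regions in both libraries' own lists. None was computed for replicate 2 alone or for the lenient lists, where more genes had regions. Within the central 95% of their random lists were Sox genes with 13 of 19 (percentile 3.85), beta-defensins with 0 of 42 (percentile 6.85) and GABA-A receptor subunit genes with 10 of 15 (percentile 64.7). The beta-defensins could not reach a lower percentile, so they could not have fallen below.

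Replicate 2 had more regions than replicate 1. A difference in depth would raise the significance of regions of like signal, and over 7799 shared regions whose signal values differed by less than 10% the median ratio of −log10 p was 1.53 (quartiles 1.37 and 1.71). That passes the limit set for depth, but only if signal has the same scale in both lists, which the files do not state, so depth is left open. Of the 5000 regions of highest signal in replicate 2, 5 (0.10%, Wilson interval 0.0427 to 0.234) were absent from the lenient list of replicate 1, but another mix of cell types would shift signal and need not remove regions, so this does not exclude it. Of the 13151 regions of replicate 2 not found in replicate 1, 80.9% were in that lenient list, which does not decide the matter either, so the cause of the longer list stays open.

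The distal regions of highest signal value may in part be nuclear copies of mitochondrial DNA, to which mitochondrial reads can align. At least 50% of the length aligned to the mitochondrial genome in 2 of the 5 regions, and the region near Abcb11 missed that limit at 48.5%, so the test set in advance, which asked for 3, did not decide. All 4 such regions among the 17641 distal regions were among the 50 of highest signal. The regions near Pak3 and Frmd4a aligned over 0.0% of their length, which excludes this source for them. Further near-identical copies elsewhere in the nuclear genome (at least 90% identity over 80% of the length) were found for 1 of the 5, which argues against that as the general source, although 10 of the 50 highest regions had one against 0 of 50 random distal regions, and no biological explanation was tested.

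Of 104 genes of the 7 forebrain lists, 18 had no promoter region in either library. The rule that the highest summit must lie near the start site does not account for them, since 11.1% (2 genes, Nr2f2 and Sp8) gained a region in both libraries when any overlap counted. Regions that miss the IDR threshold may account for part. In the lenient lists 8 of the 18 (44.4%), Gad1, Gbx2, Gsx1, Lmx1a, Nkx2-1, Nkx2-4, Otx2 and Sp8, gained one, against 15 of the 95 genes without a region in the lists of other lineages, and the share was between the limits set for the test. These groups were not matched on promoter CpG content, with which the share of listed promoters rose. Otx2 belongs to both groups. The difference between the groups is therefore not read as one of lineage. Activity in a minority of the pooled cells was not tested and stays open.

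A hypothesis that distal regions near ganglionic eminence genes carry more TAATTA homeobox sites, and those near cortical genes more CAGATG sites, was tested by permuting genes between the lists (100000 permutations, two-sided, 18 genes with distal regions in each list). TAATTA was present in 7 of 61 regions near ganglionic eminence genes (11.5%) and 11 of 96 near cortical genes (11.5%), a difference of 0.017 percentage points (permutation p = 1.00, adjusted p = 1.00 over 2 tests). CAGATG was present in 18.0% and 24.0%, a difference of -5.93 percentage points (permutation p = 0.27, Benjamini-Hochberg adjusted p = 0.54). Neither difference was detectable with this number of genes, which does not show that the regions are alike.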
